A study of Homo sapiens with 2 samples.

How the data were processed

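RNA of 2 samples of the CL1-0 cell line was measured on Affymetrix expression arrays, 1 array per sample. The control sample carried a control vector and the other an FDFT1 expression vector. The labels describe puromycin selection for 2 weeks, growth at 37 °C in 5% CO2, and biotin-labelled cRNA made from 6 µg of total RNA. The groups were taken from the sample titles.

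The deposited values are MAS5 signal intensities on a linear scale, 1 value per probe set and array; MAS5 is named in the submitters' processing notes. MAS5 subtracts mismatch probes and scales each array as a whole. The software version, the target of the scaling, and detection calls are not given in the sources used here. The trimmed means of the deposited signals, with 2% removed at each end, were 151 on the control array and 142 on the FDFT1 array, so the arrays were not at an equal level. For arrays, the number of samples limits the precision: with 1 array per group there is no replicate, and no p-value or replicate error can be given for any gene.

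All steps described next were computed here with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The choices in this paragraph were fixed before the data were examined. The 62 control probe sets were set aside, leaving 54613. Signals were put on the log2 scale and centred on the median difference between the arrays over probe sets at or above a floor in both. This shift was -0.11 (FDFT1 minus control). The floor was the median of all signals, 12.2, and lower values were set to it, so a difference against a value under the floor is a lower bound on the centred scale. The floor is not a detection limit, and many signals just above it may be background. A probe set was measured if the higher of its signals reached the floor. A gene took the value of its brightest measured probe set. A size of at least 2-fold (1 on the log2 scale) was the rule for counting a gene as higher or lower.

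Gene names came from the platform annotation given with the value table. It listed 1 gene for 41091 probe sets, several genes for 1801, and none for 11721. Only probe sets with 1 listed gene were used for genes; 41037 of them had an Entrez identifier in the GRCh38.p14 gene table, and no symbol needed updating. The named probe sets covered 19775 genes, of which 12962 were measured. Some genes, including FDFT1, had no probe set under their own name in this annotation and were not analysed here. For the same reason 2 of 5 genes fixed individually in advance have no value.

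The genes named in the text followed a fixed rule. They are up to 13 genes each way with the largest change among those changed at least 2-fold with at least 2 measured probe sets that all moved the same way, the 5 largest each way among genes with 1 measured probe set, up to 2 measured members of each gene list with the largest difference above 0 and up to 2 with the largest below 0, and 5 genes fixed individually. Other list members are named as examples and were chosen after their values were seen. Of the 30 gene lists fixed beforehand, 27 had at least 5 measured members. The median log2 difference of such a list was placed among those of 10000 random gene lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5; this describes these 2 arrays and is not a test of the condition. By chance 1.35 of 27 lists would stand apart.

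The error of a probe set was estimated from genes with at least 2 measured probe sets, as the SD of the difference between the brightest and the second brightest, divided by the square root of 2. Splitting it by signal was chosen after the arrays had been compared. It covers probe-level error and differences between transcripts, not differences between cultures. Alternatives were another scaling (values as deposited, quantile, loess), no floor or a floor at the 75th percentile (signal 99.5), the mean of a gene's probe sets, leaving out probe sets whose identifiers end in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, list means, and unmatched random lists.

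The steps were tested on simulated data: 1 pair of arrays for 13063 genes with the spread of the real FDFT1 and control arrays and 200 genes changed by known folds. The changed genes were drawn only from genes with a mean signal well above the floor. Of 50 such genes changed 2-fold, 66% were counted as at least 2-fold, of 50 changed 3-fold 98%, and of 50 changed 4-fold 100%. These rates do not apply to dim genes. A list of 12 genes from the same brighter pool, lowered by 0.3 on the log2 scale, was placed at percentile 0.04. Of 200 unchanged lists 4.5% stood apart. Noise was drawn independently for each probe set, so trends shared between genes were left out. Among the unchanged genes 62 were counted as higher and 72 as lower; the simulated noise was drawn from the spread of the real pair, so these counts exclude nothing about the real arrays.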

Results

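Expression was compared between CL1-0 cells carrying an FDFT1 expression vector and CL1-0 cells carrying a control vector, with 1 array for each. CL1-0 is an established human lung adenocarcinoma line, described in the labels as of type II alveolar origin. FDFT1 encodes squalene synthase, the enzyme that makes squalene from farnesyl pyrophosphate and commits the mevalonate pathway to sterols. Each array reported 54675 probe sets. The median MAS5 signal was 12.3 on the control array and 12.1 on the FDFT1 array, and the 75th percentiles were 104 and 95.4. Over the 14083 probe sets that reached a signal of 99.5 on at least 1 array, the log2 signals of the 2 arrays correlated with a Pearson r of 0.989 across probe sets. As there were no replicates, each difference compares these 2 arrays and carries no p-value.

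Signs of RNA integrity were close on the 2 arrays. The ratio of the 3′ to the 5′ control probe set was 0.959 on the control array and 1.01 on the FDFT1 array for GAPDH, and 1.16 and 1.15 for ACTB. The 18S ribosomal RNA control probe sets were higher on the FDFT1 array by 0.48 on the log2 scale (3 probe sets, range 0.34 to 0.72). The hybridisation controls bioB, bioC, bioD and cre were at -0.23, -0.22, -0.05 and -0.03, and the lys, phe, thr and dap controls lay between 0.0046 and 0.08. FDFT1 itself was not analysed here, so the overexpression was not checked from these arrays.

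Few transcripts differed by much between the 2 arrays. Of 12962 measured genes, 11623 (89.7%) differed by less than 0.5 on the log2 scale. At least 2-fold higher signals with FDFT1 were found for 70 genes (0.54%) and at least 2-fold lower signals for 74 (0.571%). Most of these genes were dim, since 53 of the 70 and 58 of the 74 had a mean signal under 32. With the floor at a signal of 99.5, 3 of 8059 genes were at least 2-fold higher and 2 were lower. Without centring of the arrays, the split was 45 higher and 106 lower.

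**Figure D1:**
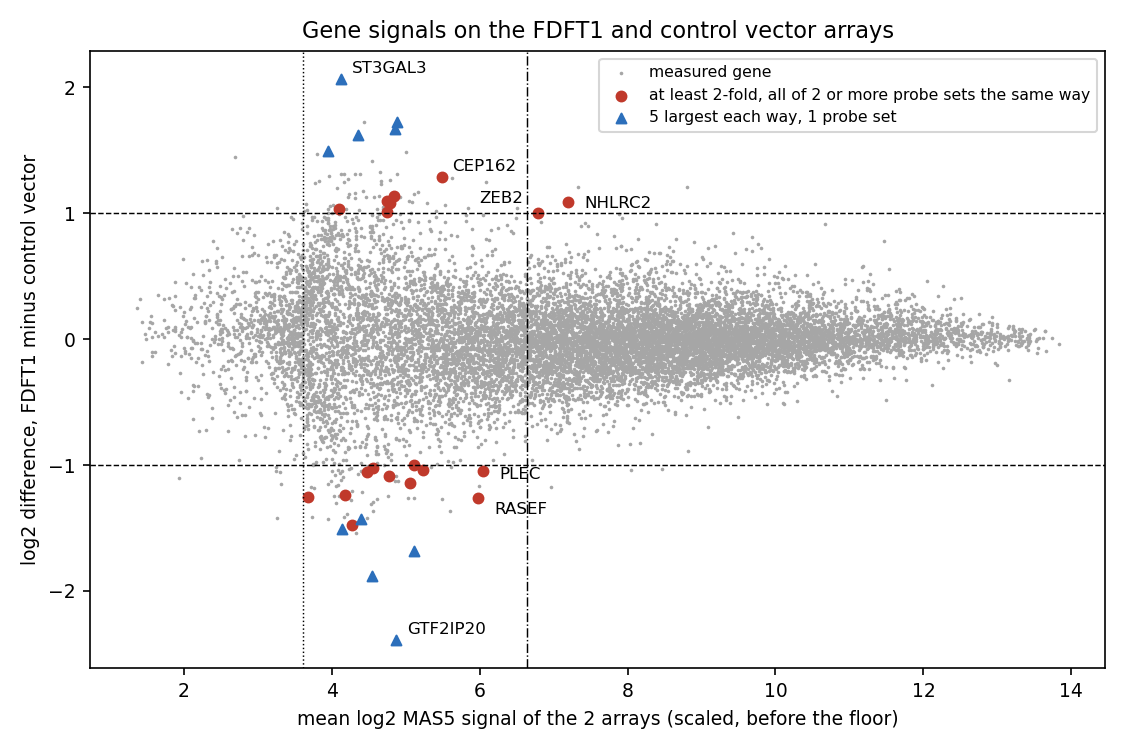
Log2 difference (FDFT1 minus control vector, floored signals) against mean log2 MAS5 signal for 12962 measured genes, 1 array per group. Dashed lines mark 2-fold, the dotted line the floor at a signal of 12.2 and the dash-dotted line the floor at 99.5; red points are genes at least 2-fold different whose probe sets (at least 2) all moved the same way, and blue triangles the 5 largest each way among genes with 1 probe set, nearly all of them at low signal.

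The spread between probe sets of the same gene sets the scale for these differences. Over 6529 genes with at least 2 measured probe sets, the differences of the brightest and the second brightest correlated weakly across genes (Pearson r 0.088, Spearman rho 0.11). The error of a probe set's log2 difference was taken from genes whose 2 brightest probe sets fell in the same signal range, which leaves out most of these genes (513, 765, 884, 503 and 209 genes from the dimmest to the brightest range). It was 0.48 for mean log2 signals under 5, 0.30 from 5 to 7, 0.22 from 7 to 9, 0.16 from 9 to 11 and 0.097 above. In the dimmest range the SD of all gene differences was 0.47, so a change of 1 there is about 2 such errors. The differences of the 2 probe sets did not correlate in that range (Pearson r -0.015). In the brighter ranges r was 0.20, 0.21, 0.18 and 0.15, from dimmer to brighter. Where a gene is named with 1 value under the floor, its difference is a lower bound on the centred scale only. Among the list members named below, these were IDI2, TNFAIP2, CXCL1, ICAM1, MMP1, MMP2, CLDN3, ITGA3, EGLN3, ARHGEF17, AXL, MUC5AC, ITGAM and CD3E. Signals given from the control to the FDFT1 array are as deposited, whereas folds and differences are centred, so the signals alone give smaller increases and larger decreases. Genes are not replicates, and these errors leave out variation between cultures.

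For genes at least 2-fold different, the second brightest probe set had the same sign in 57.9%, against 55.2% of all pairs. Agreement of probe sets in sign therefore adds little support to the genes named next. Among the genes at least 2-fold higher, 18 had at least 2 measured probe sets, and in 8 of these all were higher. CEP162, a centrosomal protein of the ciliary transition zone, was the first of these by size, 2.44-fold (29.8 to 67.6, error 0.30 on the log2 scale). TMEM67, also a transition zone protein, was 2.2-fold higher and CFAP69, a cilia and flagella associated protein, 2.14-fold. NHLRC2 was 2.13-fold higher (104 to 206) with 3 of 3 probe sets higher, and ZEB2, a repressor of E-cadherin transcription, 2.0-fold (80.9 to 151) with 3 of 3. TNRC6C-AS1 was 2.12-fold higher, IKZF1, a lymphoid transcription factor, 2.01-fold, and CAMK1D at least 2.04-fold against the floor after centring (0.98 on the log2 scale without it). Without centring, 6 of these 8 genes fell short of 2-fold, at 0.90 to 0.99 on the log2 scale, and with the mean of all probe sets 6 did, at 0.53 to 0.64. Without _x_at and _s_at probe sets ZEB2 was at 0.36 and TNRC6C-AS1 at 0.034. For TMEM67, CFAP69 and TNRC6C-AS1, 1 probe set lay at only 0.077, 0.018 and 0.034. As deposited, these signals were lower on the FDFT1 array, so their sign comes from the centring. Among genes with 1 measured probe set, the largest values were ST3GAL3, a sialyltransferase, at least 4.20-fold, FGG, the fibrinogen gamma chain, 3.30-fold, RNF121 3.18-fold, HTR4 at least 3.08-fold and FGF6 at least 2.81-fold; all 5 had signals under 52 on the FDFT1 array.

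Among the genes at least 2-fold lower, 20 had at least 2 measured probe sets, and in 11 of these all were lower. RASEF was 2.39-fold lower (101 to 39.2, error 0.30) and PLEC, the cytolinker plectin, 2.06-fold lower (98.1 to 44.2). CHST5, a sulfotransferase, was at least 2.79-fold lower, GNB1L at least 2.39-fold and TSNARE1 at least 2.36-fold. SPPL2B, an intramembrane protease, was 2.21-fold lower with 3 of 3 probe sets below 0, but the others lay at -0.00071 and -0.35. IL18BP, the interleukin-18 binding protein, was 2.12-fold lower, SYT7 2.08-fold, UNC93B1, a chaperone of endosomal Toll-like receptors, 2.06-fold, SH2D3C 2.03-fold and MELTF-AS1 2.0-fold. With the mean of all probe sets, 8 of these 11 genes fell short of 2-fold, at -0.50 to -0.95, and without _s_at probe sets GNB1L was at -0.43. The other probe sets of IL18BP and SYT7 lay at only -0.022 and -0.020. With 1 measured probe set, GTF2IP20 was 5.24-fold lower, ZNF414 at least 3.69-fold, COQ8B 3.21-fold, LINC01138 at least 2.84-fold and CHRNB2 2.69-fold. GTF2IP20 is a pseudogene whose probe set can match related copies, so its value is uncertain; the same limit applies to the _x_at probe sets of CHST5, TNRC6C-AS1 and MELTF-AS1.

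With the floor at 99.5, the 3 higher genes were ZFX, 2.32-fold (110 to 236), ITFG1, 2.31-fold (306 to 657), and NHLRC2, 2.13-fold. Over all measured probe sets, 3 of 5 were higher for ITFG1 and 2 of 4 for ZFX. The ZFX value came from an _x_at probe set, so the limit given above for such probe sets applies to it too. The 2 lower genes were BATF3, 2.04-fold lower (525 to 239), and the pseudogene POTEKP, 2.05-fold lower. These were named after their values were seen, apart from NHLRC2.

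The enzymes around squalene synthase showed no member at least 2-fold different. Upstream, 2 of the 8 measured mevalonate enzymes were above 0 and 6 below, with a median of -0.07 (percentile 16.6). MVD, the mevalonate decarboxylase, was at -0.24 and IDI1, the isopentenyl diphosphate isomerase, at -0.18 (1787 to 1468), while MVK was at 0.16. IDI2 was at 0.18 with its control signal under the floor (6.6 to 13.3), so it may be background. FDPS, which makes the substrate of squalene synthase, was at -0.02 (2929 to 2680). Downstream, 5 of 10 measured enzymes were above 0 and 5 below, with a median of -0.03 (percentile 35.0); without _x_at and _s_at probe sets the 6 enzymes left had a median of -0.21 (percentile 0.48). LSS, the lanosterol synthase, was at -0.40 (434 to 305, error 0.22, 3 of 3 probe sets lower) and NSDHL at -0.30, whereas LBR was at 0.35 (1275 to 1512, error 0.16) and DHCR7 at 0.15. SQLE, the squalene epoxidase that follows squalene synthase, was at 0.09 (649 to 643), with 2 of its 4 probe sets higher.

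Genes of sterol sensing and cholesterol uptake were lower as a list. Of 12 measured members 9 were below 0, and the median of -0.19 lay at percentile 0.44, against a 95% range of -0.14 to 0.12 for random lists. No member reached 2-fold. The lowest were SREBF1 at -0.47 (269 to 181, error 0.22, 1 of 2 probe sets lower) and SREBF2 at -0.45 (76.5 to 51.9, error 0.30, 3 of 3 probe sets lower), the genes of the sterol regulatory element binding proteins. NPC1, the lysosomal cholesterol exporter, was at -0.40, SCAP, the escort protein of these factors, at -0.36 and MBTPS1, a protease that activates them, at -0.30. The highest members were STARD4 and INSIG1, both sterol-regulated, at 0.28 each. With the floor at 99.5 the percentile was 2.56, just inside the range of random lists.

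The medians of other lipid lists did not stand apart at the main settings. Fatty acid synthesis had a median of -0.02 (10 genes, percentile 33.4), from FADS2 at -0.47 and FASN, the fatty acid synthase, at -0.38 (1068 to 765, error 0.16) to ACSL4 at 0.59 and ELOVL6 at 0.46. Of 10 cholesterol efflux genes and LXR targets 9 were above 0, with a median of 0.14 (percentile 91.0), or 0.22 (percentile 98.9) with the mean of all probe sets. The exception was SCARB1, the HDL receptor, at -0.82 (395 to 208, error 0.22), where 1 of 4 probe sets was higher. SOAT1, which esterifies cholesterol, was at 0.52 with 1 of 3 probe sets higher, and ABCG2, a transporter, at 0.29. The prenylation, dolichol and ubiquinone branches had a median of 0.02 (13 genes, percentile 68.8), with GGPS1 at -0.35, DHDDS at -0.24, FNTA at 0.22 and ZMPSTE24 at 0.25.

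Squalene synthase has been studied in lung cancer cells together with lipid rafts, TNF receptor signalling and matrix metalloproteinases, and these lists were compared for that reason. Of 10 caveolar and raft proteins 7 were below 0, with a median of -0.09 (percentile 8.51). CAVIN1 was at -0.22 and FLOT1, a raft marker, at -0.17 with 4 of 4 probe sets lower, while CAV1, caveolin-1, was at 0.81 and CAV2 at 0.63 at signals under 32. TNF receptor signalling had a median of 0.02 (16 genes, percentile 74.4). TNFRSF1A, the main TNF receptor, was at -0.07 (137 to 121, error 0.22), MAP3K5 at -0.27 and TRADD at -0.23, while CHUK, a kinase of the NF-kB pathway, was at 0.38. CASP8 was at 0.58 on its brighter probe set and -0.63 on the other. The 12 measured NF-kB targets had a median of -0.11 (percentile 14.4), from ICAM1 at -0.58 and NFKB2 at -0.43 to TNFAIP2 at 0.50 and CXCL1 at 0.34. Among 13 metalloproteinase and plasminogen genes (median -0.02, percentile 40.02), MMP1, the interstitial collagenase, was at least 2.06-fold higher after centring on its 1 probe set (12.6 to 24.2 as deposited), a difference of 1.04 with an error of 0.48. It was 0.94 without centring and 0.99 after quantile normalization. PLAUR, the urokinase receptor, was at 0.67, MMP2 at -0.89 and MMP11 at -1.01, where the other MMP11 probe set lay the other way.

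**Figure D2:**
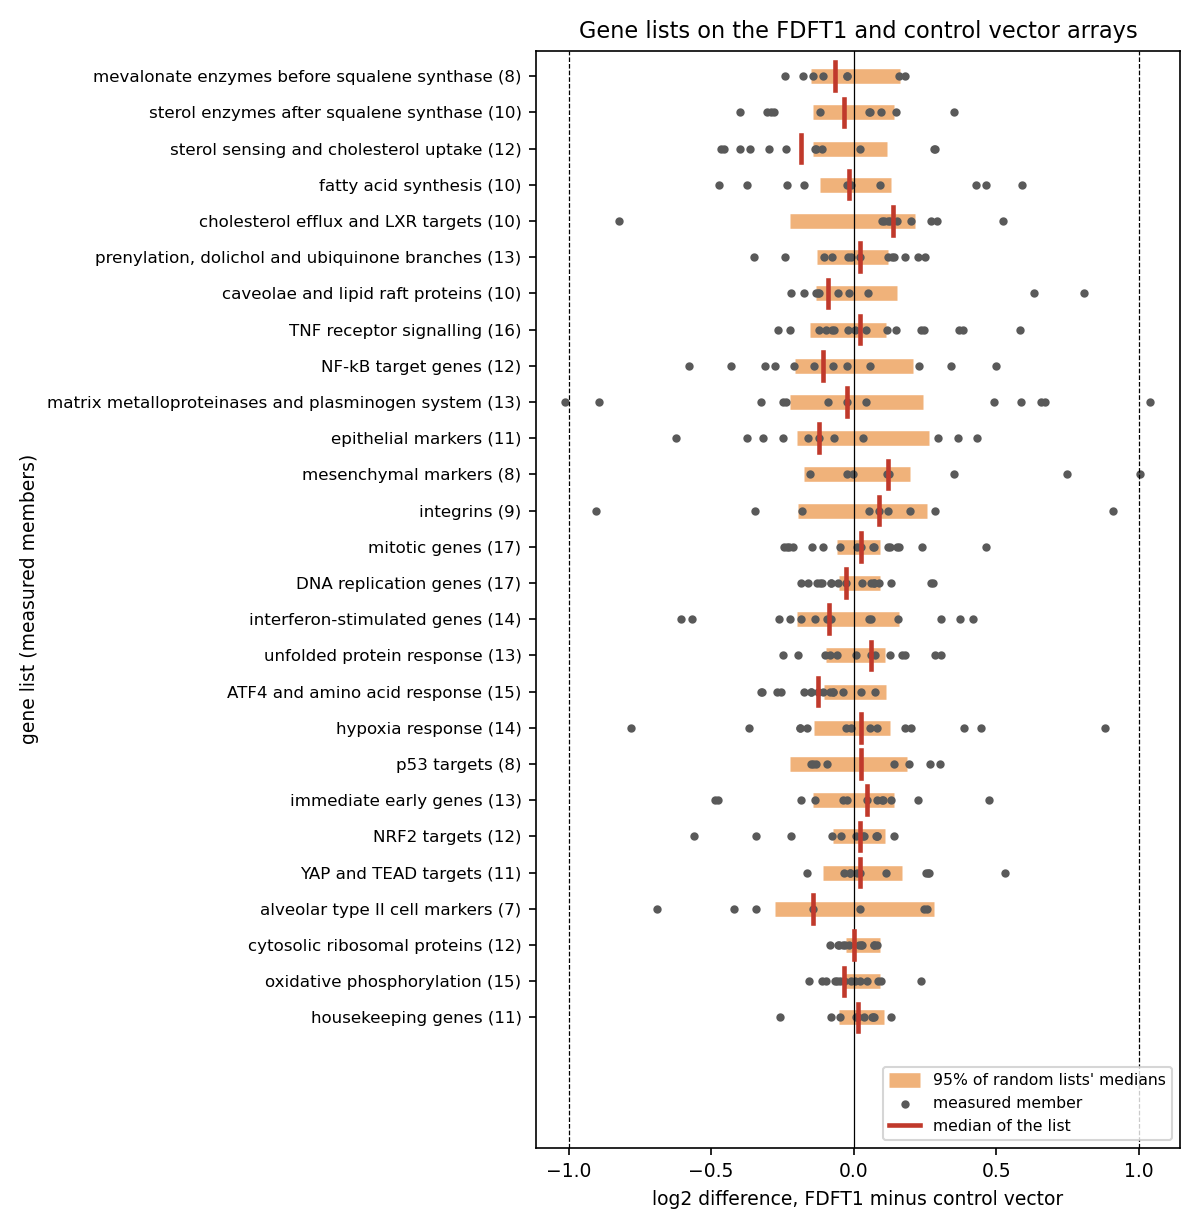
Log2 difference (FDFT1 minus control vector) of each measured member of 27 gene lists (grey points), with the list's median (red bar) and the range that holds 95% of the medians of 10000 random lists matched on signal (orange), 1 array per group. The medians of the sterol sensing list at -0.19 and of the ATF4 list at -0.13 lie outside their ranges.

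The medians of epithelial and mesenchymal markers did not stand apart at the main settings. The 11 measured epithelial markers had a median of -0.12 (percentile 8.74), with the keratin KRT18 at -0.62 and CLDN3 at -0.38 but KRT8 at 0.43 and KRT7 at 0.37, each on 1 dim probe set. The 8 measured mesenchymal markers had a median of 0.12 (percentile 88.7) and a mean of 0.27 (percentile 99.0). Besides ZEB2, SNAI1 was at 0.75, while ZEB1 was at -0.15, FN1 at -0.02 and VIM, vimentin, at 0.12 (8101 to 8162). The integrins had a median of 0.09 (9 genes, percentile 76.6), from ITGA5 at -0.90 and ITGA7 at -0.35 to ITGA3 at 0.91 and ITGB4 at 0.28, each at signals under 40. Of 13 alveolar type II markers 7 were measured, with a median of -0.14 (percentile 16.6), or -0.27 (percentile 1.58) with the mean of all probe sets. SFTPC, surfactant protein C, was at -0.69 (29.3 to 16.9, error 0.48) and ABCA3 at -0.42 (79.9 to 55.6, error 0.30). LAMP3 was at 0.26 and SFTPB at 0.25 (31.97 to 35.25, error 0.30). NKX2-1 was as dim (31.1 to 29.3), while ETV5 (383 to 281) and LPCAT1 (934 to 787) were brighter. The signals of SFTPC, SFTPB and NKX2-1 may be background, so these signals do not bear out the type II origin given in the labels.

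Markers of other cell types were mostly unmeasured. Of 13 blood and immune markers 4 were measured, with HBB at 0.58, ITGAM at 0.27, CD3E at 0.18 and CD79A at -0.21. Of 14 fibroblast and endothelial markers 4 were measured, with COL1A1 at 0.45 (1 of 3 probe sets higher), PECAM1 at 0.41 and DCN at -0.15. POSTN, the brightest of them, was at 0.24 (694 to 760, error 0.16, 1 of 2 probe sets higher). Of 10 airway and squamous markers 3 were measured: MUC5AC was at -1.08 at a signal of 27 on the control array, where its other probe set lay the other way, SOX2 was at -0.02 (3906 to 3572) and MUC1 at 0.11.

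Genes of the ATF4 and amino acid response were lower as a list. Of 15 measured members 13 were below 0, and the median of -0.13 lay at percentile 1.16, against a range of -0.10 to 0.11 for random lists. CHAC1 was at -0.33, DDIT4 at -0.32, SLC7A5, an amino acid transporter, at -0.27 (1392 to 1072, error 0.16) and PHGDH, the first enzyme of serine synthesis, at -0.26 (1301 to 1013, error 0.16). SLC3A2 was at 0.08 and VLDLR at 0.03. ATF4 itself was at -0.07. Leaving out the _x_at and _s_at probe sets left 8 members at percentile 4.46, and random lists not matched on signal gave percentile 4.71, both inside the range. The list was also inside the range, at percentile 5.64, once a trend shared with genomic neighbours was subtracted.

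Proliferation genes were bright on both arrays. The 17 mitotic genes had a median of 0.02 (percentile 64.4), or 0.11 (percentile 99.2) with the mean of all probe sets, with KIF11 at 0.46 and AURKA at 0.24 at the top and CDK1 at -0.25 and AURKB at -0.23 at the bottom. The other probe sets of these last genes lay the other way, at 0.07, 0.08 and 0.28 for CDK1 and 0.46 for AURKB. The 17 DNA replication genes had a median of -0.03 (percentile 10.99), from MCM2 at -0.19 and MCM3 at -0.16 to RRM1 at 0.27 and MCM4 at 0.28.

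Stress and signalling lists other than the ATF4 list did not stand apart at the main settings. The unfolded protein response had a median of 0.06 (13 genes, percentile 88.2; DNAJC3 0.31, XBP1 0.28, PDIA4 -0.25, CRELD2 -0.20). Interferon-stimulated genes had a median of -0.09 (14 genes, percentile 23.4), with IRF9 at -0.61 and IFI44 at -0.57 but IFIT3 at 0.42 and IFIT2 at 0.37. In the hypoxia list (14 genes, median 0.02, percentile 69.7), SLC2A1, the glucose transporter GLUT1, was at 0.88 and EGLN3 at 0.45, PFKFB4 at -0.78 and ANKRD37 at -0.37. The p53 targets had a median of 0.02 (8 genes, percentile 67.7), with SESN1 at 0.30, RRM2B at 0.27, TP53I3 at -0.15 and ZMAT3 at -0.14, where 4 of 5 ZMAT3 probe sets were higher, 1 of them at 1.35 (45.8 to 109). The immediate early genes were at 0.05 (13 genes, percentile 77.7), with EGR1 at 0.47, EGR3 at 0.23, DUSP5 at -0.49 and JUN at -0.48. The NRF2 targets were at 0.02 (12 genes, percentile 58.9), with GCLC at 0.14, TXNRD1 at 0.08, OSGIN1 at -0.56 and AKR1C3 at -0.34. The YAP and TEAD targets were at 0.02 (11 genes, percentile 47.2), with ARHGEF17 at 0.53, AMOTL2 at 0.26, AXL at -0.16 and F3 at -0.04.

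Reference genes differed little. The 12 measured ribosomal protein genes lay between RPL8 at -0.08 and RPL27 at 0.08 (percentile 17.9), with RPL3 at -0.06 and RPL11 at 0.07. The oxidative phosphorylation genes had a median of -0.03 (15 genes, percentile 3.41), with NDUFV1 at -0.16, SDHA at -0.11, ATP5F1B at 0.10 and NDUFS1 at 0.24. The 11 housekeeping genes had a median of 0.02 (percentile 46.3), with TBP at -0.26, B2M at -0.08, HPRT1 at 0.13 and TFRC at 0.07. Of the 116 list members named by the fixed rule 50 had at least 2 measured probe sets, and 33 of these had a probe set that lay the other way. For 21 at least as many lay the other way as with the printed value: besides those given above with their probe sets (SREBF1, SOAT1, CASP8, MMP11, CDK1, AURKB, ZMAT3, MUC5AC and COL1A1), these were DHCR7, FNTA, GGPS1, TRADD, PLAUR, FN1, RRM1, IFIT3, IFI44, DNAJC3, JUN and SFTPB. Directions of lists and genes are relative to the centring of the arrays; without it the median of all genes was -0.10 on the log2 scale. The median and the mean had opposite signs for fatty acid synthesis, caveolae, metalloproteinases, DNA replication genes, immediate early genes and NRF2 targets.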

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

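The counts of probe sets by annotation and the tests of the genes at least 2-fold different, of sterol-regulated transcripts in general, of gene length at a given signal and of dim ATF4 list members were chosen only after the result was seen. The annotation used here left part of the array out of all gene comparisons, and a signal there stood out. Of 795 probe sets with no listed gene that reached a signal of 99.5, 5 were at least 2-fold higher on the FDFT1 array and 1 was lower. That is 0.629% higher and 0.126% lower, against 0.0797% and 0.0319% of the 12551 probe sets with 1 listed gene, and it rests on few probe sets. At the main floor the excess was smaller: 1.40% of 3579 probe sets with no listed gene were higher and 1.03% lower, against 0.768% and 0.703% of those with 1 gene. These shares were not matched on signal. The probe sets with no listed gene were dimmer, as 795 reached 99.5 and 3579 the main floor, against 12551 and 24615 with 1 gene. Dim signal therefore stays open as a source of the excess. Which transcripts these probe sets measure was not analysed here.

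The genes at least 2-fold different were mostly dim and mostly measured by 1 probe set. The second brightest probe set had the same sign for 22 of 38 of them with at least 2 (57.9%, exact 95% interval 40.8 to 73.7%), against 55.2% of all 6529 pairs, so error of probe sets could account for many of these genes. It was at least 2-fold different the same way for 4 genes and the opposite way for 3, where the rate among second probe sets of like signal would give 0.763 each. The excess was much the same both ways, so it does not tell error from a shared change for the 4. They were RASEF, PLEC, IKZF1 and MELTF-AS1, and MELTF-AS1 rests on _x_at probe sets only. Probe sets of a gene can also measure different transcripts. RNA degradation that differs between the arrays would move the 3′ to 5′ ratios, and the larger change of GAPDH and ACTB was 0.068 on the log2 scale, which argues against it. An effect of FDFT1 on single genes stays open, since array and condition cannot be told apart with 1 array each.

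The sterol sensing and ATF4 lists had lower medians than matched random lists, where chance would place 1.35 of 27 lists apart and 2 were found. For the sterol sensing list, the second brightest probe sets of 8 members gave a median of -0.25 at percentile 1.73, the genomic neighbours of the members lay at percentile 74.3, and random lists matched on gene span in place of signal left it at percentile 0.98, and on both at 0.49, so error of a few probe sets, a regional trend and gene length do not account for the whole difference in these tests. Whether sterol-regulated transcripts were lower in general stays open, as the 18 enzymes before and after squalene synthase had a median of -0.07 at percentile 10.6. For the ATF4 list, matching on gene span in place of signal was the test of gene length fixed beforehand. It gave percentile 5.9, inside the range set for gene length as the cause, but it also dropped the matching on signal. Matched on both in 5 bins each, a test chosen after the result was seen, the list lay at percentile 1.65. The 2 tests differ, so gene length stays open for this list. The second probe sets of 5 members (percentile 14.4) and the neighbours (percentile 24.2) decide nothing. The 13 brighter members alone stayed at percentile 1.5, which argues against dim members as the source. A response to FDFT1, a difference between cultures, base composition of the transcripts and chance are untested for both lists.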

How the results depend on the processing

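Subtracting the trend of genomic neighbours was chosen only after the data were seen; the other alternatives were fixed before. The counts of 70 higher and 74 lower genes became 5 and 3 at 3-fold, 502 and 419 at 1.5-fold, 2262 and 1924 with no floor, and 3 and 2 with the floor at the 75th percentile; the values as deposited gave 45 higher (29.8% of such genes, against 48.6%). Quantile normalization kept 64 of the higher and 73 of the lower genes, and loess 64 and 71. The sterol sensing list went inside the range of random lists with the 75th percentile floor (-0.13, 10 genes, percentile 2.56). The ATF4 list did so against unmatched lists (-0.13, percentile 4.71), without _x_at and _s_at probe sets (-0.12, 8 genes) and with the neighbour trend subtracted (-0.092, percentile 5.64). Going outside it were the mesenchymal markers by the mean (0.27), the efflux and LXR genes (0.22), mitotic genes (0.11) and alveolar type II markers (-0.27) with the mean of all probe sets, and the enzymes after squalene synthase without _x_at and _s_at probe sets (-0.21, 6 genes); the cause was not tested. MMP11 reversed to 0.72 without these probe sets, where its other probe set takes its place. Of the remaining values of named genes under the alternatives, 806 stayed the same, 50 moved, 33 no longer reached 2-fold and 7 newly did. The alternatives for FDFT1 itself were not run, as it was not analysed here. No paired analysis was possible because each group has 1 array, and for that reason none could be left out. Signal over background limits the dim genes most.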

Other observations

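The gene families and the trend along chromosomes were examined only after the arrays had been compared, and the test of dim genes near the floor was chosen after the trend was seen. Of 30 gene families defined by symbol, 27 had at least 8 measured genes and 2 stood apart, against 1.35 by chance. The 17 measured protocadherins, cell adhesion proteins, had a median of -0.23 (percentile 2.08), with 10 below 0, PCDHB18P at -1.06 and PCDHGB5 at 0.82. The 404 zinc finger genes named ZNF had a median of 0.01 (percentile 98.0), from ZNF414 at -1.88 to ZNF682 at 1.28. The 29 aminoacyl tRNA synthetases had a median of -0.05 at percentile 4.53, from VARS1 at -0.48 to VARS2 at 0.14. The 30 measured histone genes had a median of -0.09 (percentile 7.65), from H3C3 at -1.29 to H1-3 at 1.14. Of 56 cilia and flagella associated genes 34 were above 0, with a median of 0.06 (percentile 90.4), from CFAP410 at -1.37 (2 of 3 probe sets lower) to CFAP69 at 1.09. These directions are relative to the centring, and families were not run under other scalings.

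Genes next to each other on a chromosome tended to differ the same way between the 2 arrays. Across 12933 genes, which are not independent replicates, a gene's log2 difference correlated with the mean of its 10 nearest measured genes on each side (Spearman rho 0.18, Pearson r 0.16), while the highest rho of 100 shuffles was 0.031. Chromosome medians lay below the range of 95% of random gene sets for 5 of 23 chromosomes and above it for 5, against 1.15 outside by chance. The lowest were chromosome 22 (-0.08, 326 genes, 62.9% below 0) and chromosome 19 (-0.07, 982 genes), and the highest chromosome 13 (0.07, 238 genes, 34.9% below 0) and chromosome 4 (0.05, 456 genes). Longer genes were higher, with medians from -0.03 among the 2587 genes of shortest span to 0.03 among the 2587 of longest span.

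Several explanations of this trend were tested. Gains or losses of whole chromosomes would leave no relation once each chromosome's median is subtracted, but rho stayed at 0.137. Gene length would leave none once a fit on gene span is subtracted, and rho stayed at 0.152. Noise of dim genes near the floor would weaken it among bright genes, and rho was 0.249 for 7247 genes with a mean log2 signal of at least 7. Base composition of the transcripts, which follows chromosomes and could act through labelling or hybridisation, and copy number differences of parts of chromosomes between the cultures were not tested here and stay open, as does an effect of FDFT1.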
